A study of Mus musculus with 6 samples.

How the data were processed

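Immune cells of mouse livers were profiled with droplet single-cell RNA sequencing and antibody tags (10x 3′ libraries, NovaSeq). Of the 6 samples, 3 are mRNA libraries, 1 per group (mock, AAV-sgSCR and AAV-sgBaat), and 3 are the antibody libraries of the same cells. The antibody samples are not held apart, and their tags were read from the mRNA matrices, where the features are CD90.1, CD90.2 and F4/80. The labels name another hashtag in place of F4/80. The protocol text names kit v2, which is uncertain beside antibody capture. According to the submitters' processing notes, reads were counted with Cell Ranger on mm10, and the matrix header gives version 6.0.1. The deposited matrices hold raw UMI counts per feature and barcode, per the file headers, with no normalization. Each deposited barcode had at least 500 gene UMIs.

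The sort, the pooling of 3 tumor samples and the 3′ chemistry set limits. T cells and other CD45hi cells were sorted apart and mixed, so shares were taken within T-like cells and within the other cells. Depth was 32005400, 62570529 and 48359443 gene UMIs for mock, AAV-sgSCR and AAV-sgBaat. With 1 library per group there is no test, p-value or standard error. Shares are given with exact Clopper-Pearson intervals and sums of counts with exact Poisson intervals at 95%, and 3 counts stand for a sum of 0.

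Analysis used Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, umap-learn 0.5.12 and matplotlib 3.10.9. Barcodes with at least 500 genes and 1000 UMIs and at most 10% mitochondrial UMIs passed (6068, 7332 and 7094). Doublet scores came from Scrublet in scanpy. Its automatic threshold called 213, 1 and 0 barcodes, so it had not worked in 2 libraries, and the highest scores were removed instead at a rate of 0.8% per 1000 barcodes (324, 465 and 429). Mixed-lineage barcodes were also removed. These were positive for the T cell panel and any other, or for the B cell panel and the monocyte and macrophage or the neutrophil panel. Other pairs of panels were kept. The panels asked for at least 2 UMIs of Cd3d, Cd3e and Cd3g, 3 of B cell genes, 4 of monocyte and macrophage genes, 10 of S100a8 and S100a9, 3 of basophil genes, 3 of plasmacytoid dendritic cell genes or 5 of granulocyte precursor genes. Together 402, 1405 and 2433 barcodes were removed.

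Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes by library were scaled, reduced to 30 principal components and joined in a graph of 15 neighbours, and Leiden clustering ran at resolution 1 with seed 0, without integration of libraries. T-like clusters were embedded and clustered again. Clusters were named from marker lists by a rule that asked for at least 60% of a class's markers to be elevated and at least 3 markers to be detected in at least 10% of cells. T-like clusters needed 5 of the T cell markers in at least 20% of cells, and a CD8 name needed 75% of gated cells to be CD8. Regulatory, gamma-delta and natural killer T cell names needed 4, 3 and 2 of their own markers. Clusters with 4 or more markers of foreign lineages stayed unassigned. Dntt/Arpp21 cells were T-like clusters with both genes at a log2 elevation of at least 2, a class that no marker list named.

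The marker lists, the 22 gene lists, the comparisons, the rule for named genes and most alternatives were fixed before the data were examined. The doublet rule, the lineage panels, the naming thresholds, the second clustering of T cells and the Dntt/Arpp21 class were not. They were settled over about 5 passes of clustering with the cell numbers per group in view, before any gene ratio or list shift was computed. CD90.1-high clusters, with a tag median at least 10 times that of mock CD8 cells, were also defined after seeing the data.

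Raw counts were summed per library and class, for classes with at least 100 kept cells in both libraries, and given as counts-per-million (CPM) of the class's gene UMIs. In CD8 T cell-like cells the genes named are the 8 highest and 8 lowest ratios of AAV-sgBaat over AAV-sgSCR and the 5 highest and 5 lowest against mock. In other classes they are 3 and 3, or 2 and 2 against mock, of which the text prints a part. Eligible genes had at least 20 UMIs and 10 cells with a UMI in the library with the higher value. Ranking set sums under 3 to 3. Hepatocyte, haemoglobin, mitochondrial, ribosomal, receptor, immunoglobulin, unnamed, sex-linked and class marker genes were left out. Up to 4 members of each list with the largest ratios and 13 fixed genes (Baat, Cd8a, Cd8b1, Pdcd1, Tcf7, Tox, Gzmb, Gzma, Prf1, Ifng, Mki67, Cxcr6 and Thy1) were named too. With 1 to 3 counts the plain ratio is printed with its interval.

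A list's shift is the median log2 ratio of members with at least 20 UMIs over both libraries, set among 10000 random lists of the same size from 20 expression bins, with a range from 2000 Poisson draws. The lists cover cytotoxic, inhibitory, naive, residency, proliferation, type I and gamma interferon, MHC class I and II, NRF2, endoplasmic reticulum stress, bile acid receptor, bile acid synthesis, immediate early, myeloid inflammatory, macrophage, glycolysis, oxidative phosphorylation, mitochondrial, regulatory T cell, T helper and chemokine genes. Outside CD8 cells, lists were picked that had an interval away from 0 and a percentile in the outer 0.5 at either end, of which the text prints a part. The rule that picks these was set after the values were seen, and the bile acid synthesis list and the neutrophil mitochondrial list are given besides. The counting was tested on simulated Poisson counts, where well-counted genes raised or lowered 1.5-fold, 2-fold and 4-fold were all placed in the right direction. The simulation held no mixture of cells and no free RNA, so it does not bear on these or on genes with few counts.

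The alternatives tried were every deposited barcode, a stricter filter (800 genes, 2000 UMIs, 5% mitochondrial), doublets kept, resolutions 0.5 and 2, another seed, T cell classes from transcripts per cell, other scalings, thinning to 1000 UMIs, equal weight per cell, list members with at least 5 or 100 UMIs, tag thresholds of 3 and 50 UMIs, and other hepatocyte sums. Keeping mixed-lineage barcodes, leaving out Dntt/Arpp21 cells, moving the unassigned barcodes, the threshold of 100 UMIs of the 2 CD90 tags together and the lists inside clusters of NK and ILC1-like, neutrophil-like, monocyte-like and B cell-like cells were added after seeing the data. The setting with doublets kept also kept mixed-lineage barcodes. Gene positions are from a RefSeq table of the mm10 assembly. An added SV40 feature was left out of the gene counts' comparisons, and sex-linked genes were not reported here.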

Results

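The series measured RNA and surface antibody tags in single immune cells of mouse livers 30 days after infection. Mice of 3 groups were compared: mock, an adeno-associated virus carrying a control guide RNA (AAV-sgSCR), and the same kind of virus carrying a guide RNA against Baat (AAV-sgBaat). Baat encodes the hepatocyte enzyme that joins bile acids to taurine or glycine. Each group is 1 library, a pool of 3 tumor samples, so no difference between groups could be tested against replicates. The labels call the mock livers native in one place and tumor bearing in another, so whether they carried tumors is left open. T cells (CD45hi CD3+) and the other CD45hi cells were sorted apart and then run together, which means that the ratio of T cells to other cells was set at the bench.

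The mock library held 6431 barcodes with 32005400 gene UMIs and a median of 4074 UMIs per barcode. The AAV-sgSCR library held 8073 barcodes, 62570529 UMIs and a median of 5454. The AAV-sgBaat library held 9386 barcodes, 48359443 UMIs and a median of 2541.5. After filters on depth, doublets and mixed lineages, 5666, 5927 and 4661 cells were kept, with median depths of 4040, 5168 and 3431 UMIs. Mixed-lineage barcodes, which paired T cell or B cell transcripts with those of another lineage, made up 5.01% of the filtered mock barcodes, 17.9% of AAV-sgSCR and 31.8% of AAV-sgBaat. Mixtures without T cell or B cell transcripts were not counted. After all filters the AAV-sgBaat values rest on 49.7% of its deposited barcodes. Shares carry exact Clopper-Pearson 95% intervals and gene ratios carry exact Poisson 95% intervals, which cover counting error only.

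Baat itself (ENSMUSG00000039653, mm10 chromosome 4, 49489416 to 49507915) was counted 7 times over all mock barcodes, 16 times in AAV-sgSCR and 1 time in AAV-sgBaat. These are 0.219 (0.0879 to 0.451), 0.256 (0.146 to 0.415) and 0.0207 (0.000524 to 0.115) CPM (counts-per-million gene UMIs). Hepatocytes were not sorted, but 11, 8 and 1 kept cells were hepatocyte-like, and the 16 AAV-sgSCR UMIs lay in 8 barcodes, so captured hepatocytes and free RNA were not told apart. Alb, the main hepatocyte transcript, was also lower in the AAV-sgBaat library, at 4.12 CPM against 33.9 in AAV-sgSCR and 4.97 in mock. A 3′ count outside an edited site checks nothing about editing. The 24 hepatocyte markers took 0.0795 of 10000 UMIs in mock CD8 T cell-like cells, 0.385 in AAV-sgSCR and 0.159 in AAV-sgBaat. Over all kept cells they took 1.02, 6.65 and 3.21, a sum that includes Hp, which neutrophils also make.

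The comparison of AAV-sgBaat with AAV-sgSCR asks how a guide against a hepatocyte bile acid enzyme bears on the T cells of the tumor-bearing liver. The T-like cells of the 2 libraries were made up of different populations. In the AAV-sgSCR library 81.6% of T-like cells were CD8 T cell-like (1961 of 2403, interval 79.998% to 83.1%), against 37.0% in the AAV-sgBaat library (723 of 1953, 34.9% to 39.2%). A population marked by Dntt and Arpp21, genes of immature lymphocytes, made up 54.5% of the AAV-sgBaat T-like cells (52.2% to 56.7%) and 3.79% of the AAV-sgSCR ones (3.06% to 4.63%). Taken as a whole class, CD8 T cell-like cells of the AAV-sgBaat library carried less RNA of inhibitory receptors, with Pdcd1 (PD-1) at 70.6 against 176 CPM. They carried more RNA of naive and memory T cell genes, with Tcf7 at 153 against 92.8.

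Leaving out the Dntt/Arpp21 cells, a choice made after seeing the data, the CD8 share was 81.3% in AAV-sgBaat (78.6% to 83.8%) and 84.8% in AAV-sgSCR (83.3% to 86.3%), and the intervals overlap. Natural killer T cell-like cells were then 5.74% in AAV-sgBaat (4.30% to 7.47%) and 3.37% in AAV-sgSCR (2.68% to 4.19%), intervals that do not meet. Overlapping were CD4 T cell-like cells at 4.61% (3.33% to 6.205%) and 2.94% (2.29% to 3.71%), gamma-delta T cell-like cells 5.96% (4.50% to 7.73%) and 4.58% (3.77% to 5.52%), and regulatory T cell-like cells 2.25% (1.38% to 3.45%) and 1.38% (0.949% to 1.95%). Over all T-like cells each of these shares was lower in AAV-sgBaat instead, at 2.61% against 3.25%, 2.10% against 2.83%, 2.71% against 4.41% and 1.02% against 1.33%, so their direction depends on whether Dntt/Arpp21 cells are counted. A further T-like cluster that took no subtype name held 67 cells of AAV-sgSCR and 1 of AAV-sgBaat. Clusters of low-UMI barcodes with mixed markers were left unassigned by a threshold set after the data were seen, and they held 10.1% of kept AAV-sgBaat barcodes, 0.0844% of AAV-sgSCR and none of mock. Counting them as T-like gave a CD8 share of 29.8% in AAV-sgBaat. The plot of T-like classes shows these shares beside mock.

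**Figure D1:**
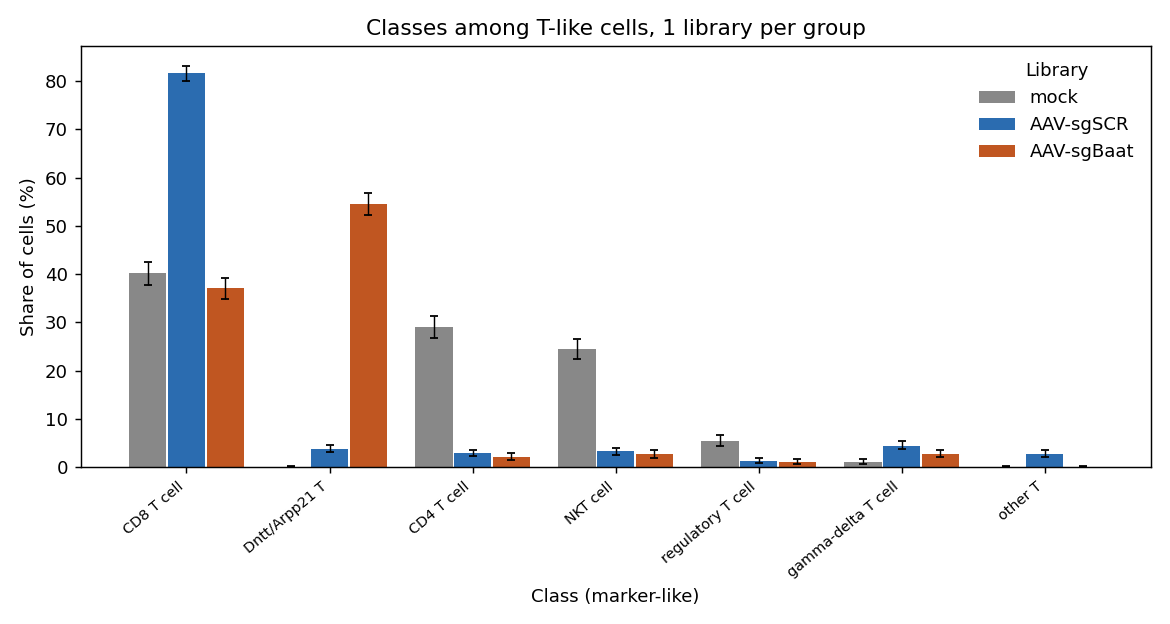
Share of T-like cells (percent, y axis) in each T-like class for the mock (grey), AAV-sgSCR (blue) and AAV-sgBaat (orange) libraries, with bars for shares and error bars for exact 95% intervals. CD8 T cell-like cells were 40.1%, 81.6% and 37.0%, and Dntt/Arpp21 T-like cells 0%, 3.79% and 54.5%.

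The Dntt/Arpp21 cells expressed Dntt (ENSMUSG00000025014, chromosome 19, 41029275 to 41059525), the polymerase that adds nucleotides at receptor junctions, at 513 CPM in AAV-sgBaat and 575 in AAV-sgSCR. Arpp21 (ENSMUSG00000032503, chromosome 9, 112065091 to 112236288) was at 289 and 356, the recombinase gene Rag1 at 94.5 and 115, the pre-T receptor gene Ptcra at 74.4 and 67.7, and the cell cycle gene Mki67 at 422 and 407. They also expressed Cd8a, at 99.8 and 159, and little Cd4, at 3.73 and 4.62. Their 1064 AAV-sgBaat cells lay in clusters 26, 30 and T15, with 366, 335 and 363 cells, the last at a median of 1554 UMIs. CD90.1 tag counts were high in them, with medians of 1961 per cell in AAV-sgBaat and 3846 in AAV-sgSCR. With 1 library per group, a cluster mostly of 1 library may be that library, not a type.

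The CD8 T cell-like cells fell into 9 clusters that the libraries filled unequally. Clusters T8 and T13, with high CD90.1 tag counts, held 23.97% and 12.1% of AAV-sgSCR CD8 cells and 0.553% and 0.277% of AAV-sgBaat ones. Cluster T12, also high in CD90.1, held 17.6% and 24.3%. Clusters T2 and T4, with low CD90.1, held 19.4% and 11.0% of AAV-sgSCR and 37.6% and 18.3% of AAV-sgBaat cells. Cluster T1, led by Ccr7 and Dapl1, held 3.77% and 7.75%, and cluster T7, led by Gzmk and low in CD90.1, held 3.16% and 0.277%. Cluster T10, led by proliferation genes, held 7.24% and 9.68%, and cluster T9, led by interferon genes, 1.73% and 1.24%. At least 100 UMIs of the CD90.1 and CD90.2 tags together, with more CD90.1 than CD90.2, a threshold chosen after seeing the data, were found in 28.9% of AAV-sgBaat, 55.5% of AAV-sgSCR and 1.68% of mock CD8 cells. At above 10 CD90.1 UMIs the shares were 97.9%, 99.1% and 88.5%, levels that B cell-like cells also reached (98.1%, 98.3% and 89.6%).

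Within the CD8 class, the 8 transcripts with the highest ratios of AAV-sgBaat over AAV-sgSCR were Arpp21, Hspa1b, Hspa1a, Hes1, Dntt, Cdr2, Cbfa2t3 and G0s2. The chaperone genes Hspa1b and Hspa1a were 17.1-fold and 15.7-fold higher in the AAV-sgBaat library, at 88.5 against 5.19 and 100.7 against 6.39 CPM. Arpp21 was counted 21 against 3 times, 25.5-fold higher (log2 2.93 to 7.06), and Dntt was at 8.11 against 1.58, 5.15-fold higher. The same library held the Dntt/Arpp21 population, and its B cell-like cells also carried Dntt, Arpp21, Gm525 and Lgals7 at a sum of 65.2 CPM, against 12.5 in AAV-sgSCR and 0.378 in mock. Hes1, a Notch target and a leading gene of cluster T15, was 5.47-fold higher, Cdr2 4.22-fold, Cbfa2t3 3.78-fold and G0s2 3.43-fold.

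Lowest against AAV-sgSCR was Ccl1, a chemokine gene with 0 UMIs in AAV-sgBaat and 394 in AAV-sgSCR, at least 36.0-fold lower. Penk, the enkephalin precursor, had 1 UMI against 168 (46.1-fold, log2 -10.84 to -3.03), C2cd4b 2 against 161 (22.1-fold, -7.52 to -2.59) and Csf1 3 against 127 (11.6-fold, -5.83 to -1.96). Igfbp7 was 18.3-fold lower, Nrn1 15.5-fold and Gpm6b 14.3-fold, and Stfa3 at least 13.6-fold with 0 UMIs against 149. Igfbp7, Nrn1, Gpm6b and C2cd4b were among the leading genes of cluster T13, which held 238 AAV-sgSCR and 2 AAV-sgBaat cells.

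Among the genes fixed for every comparison, Pdcd1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553) had a log2 ratio of -1.32 (-1.53 to -1.11) and Tox (ENSMUSG00000041272, chromosome 4, 6686353 to 6991557), a factor of exhausted T cells, -0.79. Tcf7 (ENSMUSG00000000782, chromosome 11, 52246527 to 52283383), the factor TCF-1, was at 0.72 (0.56 to 0.88), and Thy1 (ENSMUSG00000032011, chromosome 9, 44043384 to 44048579), which encodes CD90, at 0.56. Of the effector genes, Gzmb was at 0.29, Ifng at 0.38, Gzma at -0.27 and Prf1 at -0.22, whose interval spans 0. Mki67 was at 0.29, Cxcr6 at -0.12, Cd8a (ENSMUSG00000053977, chromosome 6, 71373427 to 71379171) at -0.21 and Cd8b1 at -0.12.

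Of 18 inhibitory receptor and exhaustion genes, 16 were lower in the AAV-sgBaat library, with a median log2 ratio of -0.58 (-0.80 to -0.42), below each of 10000 random lists. Cd200 was at -3.17, Tigit at -2.36 and Ctla4 at -2.06. Inside the clusters with at least 100 cells in both libraries, the median of this list was 0.02 in T2, 0.23 in T4 and -0.04 in T12. Of 15 naive, memory and progenitor genes, 11 were higher, with a median of 0.70 (0.47 to 0.75) and Klf2 at 0.92, S1pr1 at 0.82 and Lef1 at 0.79. Inside clusters this median was 0.10 in T2, -0.10 in T4 and -0.51 in T12. The cytotoxic effector list was split, with 9 of 20 genes higher and a median of -0.07 (-0.11 to 0.08), from Ccl4 at 0.69 to Klrc1 at -1.01.

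Proliferation genes were higher in 18 of 20 cases (median 0.30, with Rrm2 at 0.88 and Pclaf at 0.80), and endoplasmic reticulum stress genes in 16 of 18 (0.22, with Dnajb9 at 0.57). Immediate early and heat shock genes, which also respond to tissue dissociation, were higher in 14 of 19 (0.50, with Atf3 at 1.28 and Ier3 at 1.13). All 13 mitochondrial transcripts were lower, with a median of -0.78 (-0.84 to -0.72), mt-Atp8 at -1.38 and mt-Nd3 at -1.14. Regulatory T cell genes were lower in 8 of 9 (-0.40, with Il2ra at -2.46), myeloid inflammatory genes in 8 of 10 (-0.69, with S100a8 at -0.82) and macrophage genes in 10 of 12 (-0.59, with Spp1 at -3.38). S100a8 and S100a9 are neutrophil transcripts, and neutrophil-like cells were fewer in the AAV-sgBaat library. Spp1 was the first leading gene of CD8 cluster T13, which held 238 AAV-sgSCR and 2 AAV-sgBaat cells.

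The other lists had medians near 0 or mixed members. These were tissue residency (8 of 13 higher, 0.12, with Cd69 at 0.41 and Ahr at -1.12), type I interferon response (14 of 25, 0.04, with Oas3 at 0.59 and Ifit2 at -0.74), interferon gamma response (8 of 19, -0.01, with Irf1 at 0.55 and Serpina3g at -1.75), MHC class I (8 of 13, 0.06, with Psme2 at 0.44) and MHC class II (4 of 8, -0.04, with Cd74 at -0.30). They also include NRF2 targets (12 of 20, 0.02, with Gpx1 at 0.42 and Txnip at -0.48), glycolysis (8 of 16, -0.02, with Ldha at 0.24) and nuclear oxidative phosphorylation genes (14 of 20, 0.07, with Cycs at 0.43). T helper factors (3 of 7, -0.13, with Tbx21 at 0.42), chemokines and their receptors (5 of 11, -0.12, with Ccr2 at 0.78) and bile acid receptors and transporters (2 of 7, -0.30, interval -0.80 to 0.04, with Abcb1b at -0.96) complete them. The bile acid synthesis list had too few counted members in CD8 cells, and in cDC1-like cells all 4 measured members were lower (median -0.69), in classical monocyte-like cells 2 of 3 (-0.10) and in progenitor-like cells 2 of 3 (-0.02).

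**Figure D2:**
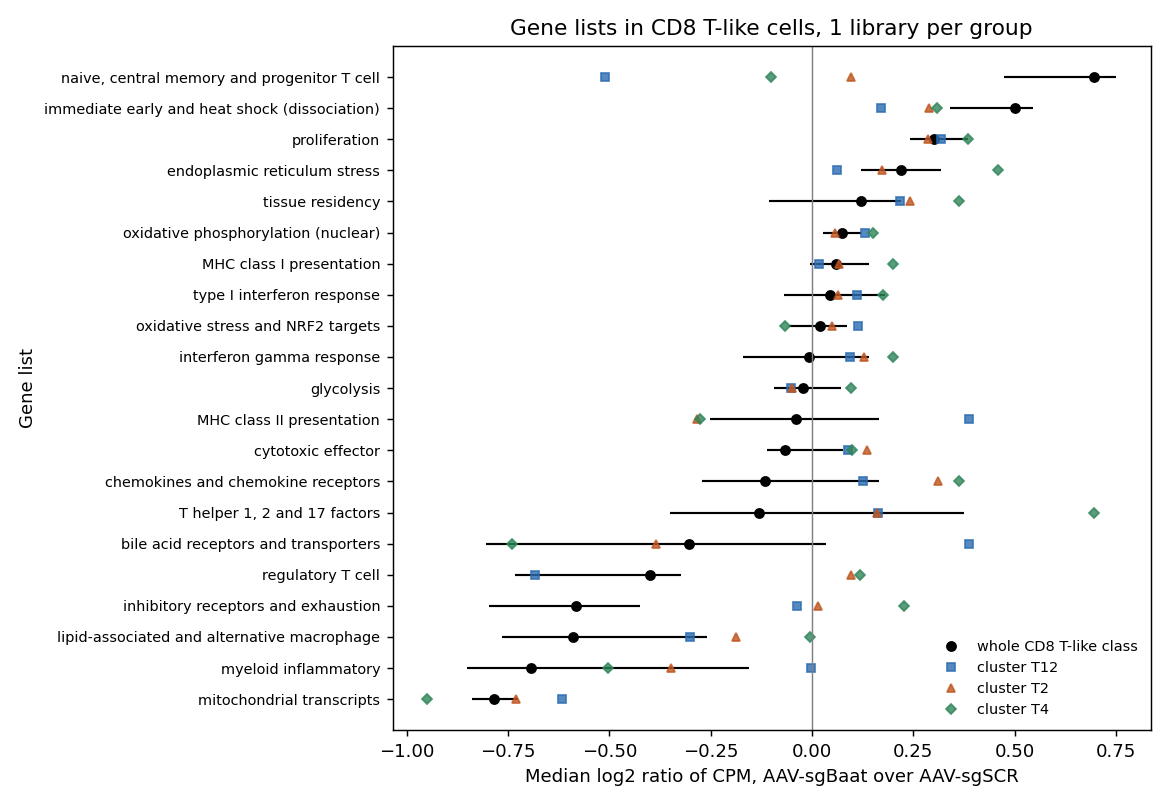
Median log2 ratio of AAV-sgBaat over AAV-sgSCR CPM (x axis) for 21 gene lists (y axis) in CD8 T cell-like cells, in black for the whole class with the 95% range of 2000 Poisson draws as error bars, and in coloured symbols inside clusters T12, T2 and T4. The inhibitory receptor list lies at -0.58 in the whole class and between -0.04 and 0.23 inside the clusters.

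Taking CD8 cells by transcripts per cell instead of by cluster also takes in Dntt/Arpp21 cells and barcodes of other classes with Cd3 and CD8 UMIs. It moved the inhibitory list to -1.71 and the cytotoxic list to -1.30. The naive list turned to -0.30, the immediate early list to -0.19, Gzmb to -0.97, Ifng to -1.12 and G0s2 to -1.14. Over all settings the medians ran from -0.70 to -0.00796 for macrophage genes, -0.74 to -0.0845 for myeloid inflammatory genes, -1.87 to -0.0523 for regulatory T cell genes, 0.00234 to 0.26 for endoplasmic reticulum stress genes, 0.29 to 1.40 for proliferation genes, -0.81 to -0.45 for mitochondrial transcripts and -0.75 to -0.0779 for bile acid receptors. Thinning cells to equal depth turned Gzmb to -0.0175, and keeping both doublets and mixed-lineage barcodes turned Gzma to 0.0481. The residency, interferon, MHC, T helper and chemokine lists took both signs over the settings tried.

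Among cells that were not T-like, the AAV-sgBaat library differed from the AAV-sgSCR library in the shares of neutrophils, macrophages, patrolling monocytes and dendritic cells. Monocyte-derived macrophage-like cells were 7.16% (6.12% to 8.31%) in AAV-sgBaat and 1.85% (1.43% to 2.35%) in AAV-sgSCR, and patrolling monocyte-like cells 3.85% (3.09% to 4.73%) and 0.682% (0.437% to 1.01%). Over the settings that named it, the patrolling monocyte-like share ran from 2.59% to 5.59% in AAV-sgBaat and from 0.577% to 2.20% in AAV-sgSCR. Migratory dendritic cell-like cells were 0.268% (0.0986% to 0.583%) in AAV-sgBaat and 3.47% (2.89% to 4.13%) in AAV-sgSCR, and type 1 dendritic cell (cDC1)-like cells 5.01% (4.14% to 5.999%) and 8.10% (7.22% to 9.05%). Type I interferon response genes were higher in AAV-sgBaat than in AAV-sgSCR classical monocyte-like and cDC1-like cells. In the main monocyte cluster their median against mock was 0.09 (-0.04 to 0.34) in AAV-sgBaat and -0.41 (-0.52 to -0.20) in AAV-sgSCR.

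Neutrophil-like cells were 19.1% (17.5% to 20.8%) of the AAV-sgBaat cells and 24.5% (23.1% to 25.9%) of the AAV-sgSCR cells, B cell-like cells 14.0% (12.5% to 15.5%) and 16.9% (15.7% to 18.2%), and NK and ILC1-like cells 14.1% (12.7% to 15.6%) and 11.1% (10.0% to 12.1%). Basophil and mast cell-like cells were 3.71% against 1.62%, immature neutrophil-like cells 3.18% against 1.96%. Plasma cell-like (1.39% and 0.654%), classical monocyte-like (15.8% and 16.2%), plasmacytoid dendritic cell-like (4.43% and 3.81%), progenitor-like (4.65% and 5.31%) and hepatocyte-like cells (0.0447% and 0.227%) overlapped in their intervals. A cluster led by pre-B genes that took no name held 3.31% and 3.69%. Keeping mixed-lineage barcodes, chosen after seeing the data, moved the AAV-sgBaat macrophage share to 44.1% (11.4% in AAV-sgSCR), the B cell share to 6.51% and the neutrophil share to 11.0%, and another seed moved the neutrophil share to 11.5% with immature neutrophil-like cells at 9.89%. Over all settings the AAV-sgBaat share ran from 2.08% to 7.02% for cDC1-like, 7.41% to 25.9% for classical monocyte-like, 1.57% to 4.77% for plasmacytoid dendritic cell-like, 2.63% to 8.20% for progenitor-like, 6.39% to 15.7% for NK and ILC1-like and 2.39% to 7.12% for basophil and mast cell-like cells. NK and ILC1-like cells were fewer in AAV-sgBaat than in AAV-sgSCR with mixed-lineage barcodes kept (6.39% against 8.61%), and B cell-like cells were more in AAV-sgBaat with the stricter filter (12.4% against 7.007%).

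**Figure D3:**
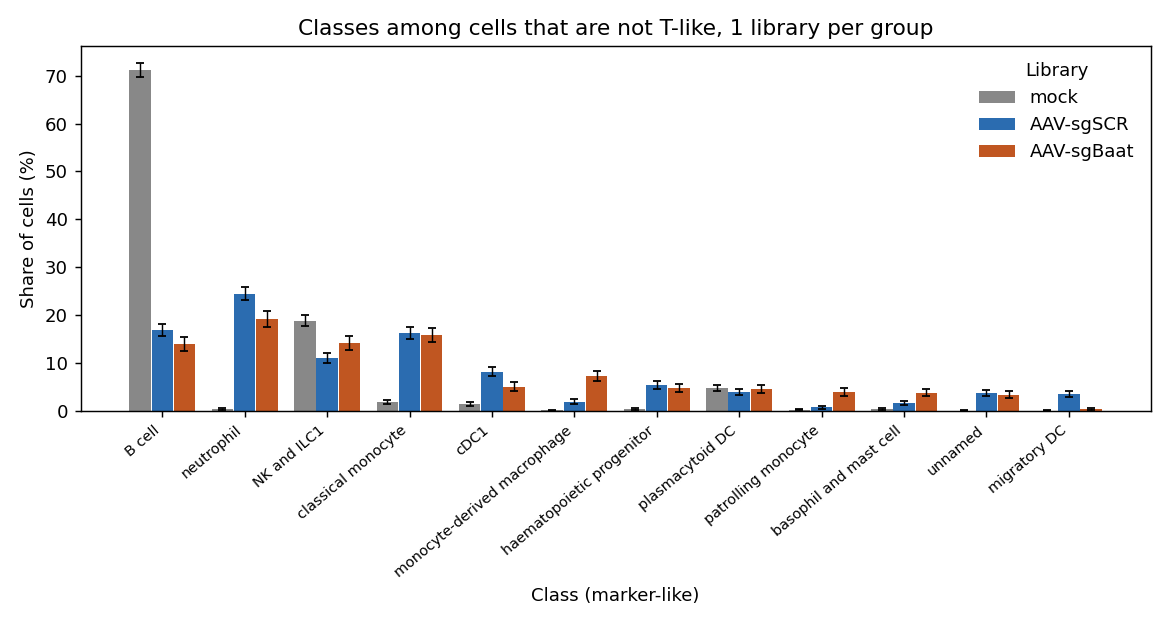
Share of cells that are not T-like (percent, y axis) in 12 classes for the mock (grey), AAV-sgSCR (blue) and AAV-sgBaat (orange) libraries, with bars for shares and error bars for exact 95% intervals. B cell-like cells were 71.2%, 16.9% and 14.0%, and monocyte-derived macrophage-like cells 0.0496%, 1.85% and 7.16%.

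In classical monocyte-like cells (353 against 571, mostly of cluster 12), 24 of 25 type I interferon response genes were higher in AAV-sgBaat, with a median of 0.65 (0.50 to 0.71), Ifit3 at 1.16 and Oas1a at 1.02. Interferon gamma response genes were higher in 15 of 17 (0.54, with the chemokine genes Cxcl9 at 2.39 and Cxcl10 at 1.47), MHC class I genes in 12 of 13 (0.38) and MHC class II genes in 8 of 8 (0.82, with H2-Eb1 at 1.60). Inside cluster 12 these medians were 0.57, 0.42, 0.41 and 0.99. Inside cluster 32 (27 against 67 cells) they were 0.23, 0.53, 0.10 and 0.08, with intervals that span 0. Against mock (71 cells), the type I interferon median inside cluster 12 was 0.09 (-0.04 to 0.34) in AAV-sgBaat and -0.41 (-0.52 to -0.20) in AAV-sgSCR. The other AAV-sgBaat medians against mock were 0.56 (-0.05 to 0.99), 0.21 (0.10 to 0.39) and 0.66 (0.45 to 0.92). Over the whole class 11 of 13 cytotoxic genes (0.63), 3 of 3 regulatory T cell genes (1.101) and 17 of 19 immediate early genes (0.25) were higher too. This cytotoxic median ran from -0.495 to 0.72 over all settings. At resolution 2, 64 AAV-sgBaat and 40 AAV-sgSCR cells of the class became macrophage-like, and 41 and 47 became patrolling monocyte-like. The MHC class II median was -0.0038 when mixed-lineage barcodes were kept. The type I interferon list was also higher in cDC1-like (19 of 22, 0.66, with Ifit3 at 4.005), progenitor-like (16 of 21, 0.85) and neutrophil-like cells (20 of 24, 0.24). In cDC1-like cells 11 of 12 naive T cell (0.62), 10 of 12 cytotoxic (0.92) and 15 of 19 immediate early genes (0.48) were higher too. Over all settings the cDC1-like cytotoxic median ran from -0.79 to 1.28. Of the neutrophil-like cells, cluster 18 held 23.4% in AAV-sgBaat and 36.4% in AAV-sgSCR, and the interferon median was 0.77 inside it and 0.17 inside cluster 23, which held the rest. Progenitor-like cells, in a cluster led by Mpo, Elane, Prtn3 and Ctsg, also had 7 of 8 myeloid inflammatory genes higher (1.54). In the same cells T cell lists were higher, with 11 of 12 naive and memory genes (0.90) and 9 of 11 cytotoxic genes (0.76), and Pf4 and Car1 were far lower, so a different make-up of the class and RNA of other cells are not told apart from a shift in each cell.

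In NK and ILC1-like cells (315 against 389), 15 of 19 cytotoxic genes were higher in AAV-sgBaat (0.23), with Ccl4 at 0.94, Ccl3 at 0.71 and Ifng at 0.60. Other medians in these cells were 0.57 for immediate early, 0.30 for type I interferon and 0.23 for endoplasmic reticulum stress genes. Those of proliferation and MHC class II genes were -0.53 and -1.11. Cluster 0, led by Klra genes, Gzma and Prf1, held 51.7% of the AAV-sgBaat and 40.6% of the AAV-sgSCR NK and ILC1-like cells, and the cytotoxic median was 0.23 inside it and 0.24 inside cluster 7, which held the rest. In B cell-like cells (312 against 594), all 8 MHC class II genes were higher (0.39). Most AAV-sgSCR and AAV-sgBaat B cells lay in cluster 2 (295 and 188) and cluster 28 (228 and 92). The MHC class II median was 0.24 inside cluster 2, -0.0175 inside cluster 6 and -0.33 inside cluster 28, so its direction depends on the cluster. Other B cell-like medians were 0.80 for proliferation, 0.50 for immediate early, 0.42 for residency and 0.31 for naive genes. Those of cytotoxic and myeloid inflammatory genes were -1.16 and -1.53. The proliferation median was 1.29 (1.14 to 1.87) over 11 genes inside cluster 28. Inside cluster 6 it was -0.61 (-1.20 to 0.04) over 4 genes, and cluster 2 had too few counted members. Hspa1a was higher in the AAV-sgBaat library in B cell-like (18.9-fold), NK (14.6-fold), cDC1-like (9.70-fold), progenitor-like (50.1-fold) and neutrophil-like cells (16.7-fold), and Hspa1b in classical monocyte-like cells (11.1-fold). All 13 mitochondrial transcripts were lower in B (-0.82), NK (-0.82), cDC1 (-0.67), monocyte (-0.74) and progenitor-like cells (-0.73), but 5 of 13 were higher in neutrophil-like cells (-0.09).

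Among the highest in AAV-sgBaat cells of other lineages were the T cell genes Cd3e in cDC1-like (10.3-fold), Trat1 in progenitor-like (8.26-fold), Bcl11b in monocyte-like (7.15-fold) and Lef1 in neutrophil-like cells (12.2-fold), while Cd8a and Cd8b1 were lower in neutrophil-like cells (-1.34 and -1.20, with intervals that span 0). At least 2 UMIs of Cd3 genes were found in 48.2% of the AAV-sgBaat and 27.1% of the AAV-sgSCR barcodes with neutrophil transcripts, at median depths of 3086 and 6449 UMIs. Lower in AAV-sgBaat were the platelet gene Pf4 (0 against 2035 UMIs, at least 153-fold) and Car1 (95.01-fold) in progenitor-like cells, Il1r2 in monocyte-like cells (25.7-fold), Ngp in cDC1-like cells (10.8-fold), the metallothionein gene Mt1 in neutrophil-like cells (9.49-fold) and Ctse in B cell-like cells (5.61-fold). The complement gene C1qa was 6.79-fold higher in monocyte-like cells. Keeping both doublets and mixed-lineage barcodes turned Cd3e in cDC1-like cells to a log2 ratio of -0.66.

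The comparison of AAV-sgSCR with mock shows how livers given the control virus differed from mock livers. Immune cells of the AAV-sgSCR library were richer in CD8 T cells and myeloid cells and poorer in B cells, CD4 T cells and natural killer T cells. CD8 T cell-like cells were 81.6% of T-like cells against 40.1% in mock (37.7% to 42.6%), and B cell-like cells were 16.9% of the other cells against 71.2% (69.8% to 72.6%). Taken as a whole class, the AAV-sgSCR CD8 cells carried more RNA of inhibitory receptors and residency genes and less of naive genes, with Pdcd1 at a log2 ratio of 3.27 and Tcf7 at -2.02. These whole-class values mix clusters that the libraries filled unequally, and mock nearly lacked the CD90.1-high clusters.

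CD4 T cell-like cells were 2.83% of T-like cells in AAV-sgSCR and 29.0% in mock, and natural killer T cell-like cells 3.25% and 24.4%. Regulatory T cell-like cells were 1.33% and 5.33%, and gamma-delta T cell-like cells 4.41% and 1.103%. Over all settings the regulatory T cell-like share ran from 0.770% to 4.90% in AAV-sgSCR and from 2.46% to 7.31% in mock. At resolution 2 the gamma-delta shares were 6.69% and 5.58%, since 72 mock NK and ILC1-like cells joined that class. Of 1632 mock T-like cells 0 were Dntt/Arpp21 cells, for which the exact interval allows a share of up to 0.226%. Neutrophil-like cells were 24.5% against 0.273% in mock, classical monocyte-like cells 16.2% against 1.76%, cDC1-like cells 8.10% against 1.36%, progenitor-like cells 5.31% against 0.372%, and NK and ILC1-like cells 11.1% against 18.8%. Plasmacytoid dendritic cell-like cells were 3.81% (3.20% to 4.49%) against 4.66% (4.03% to 5.36%).

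The CD8 cells lay in different clusters, with 45.6% of mock cells in T1 and 23.97% of AAV-sgSCR cells in T8. The CD90.1-high clusters T8, T12 and T13 held 23.97%, 17.6% and 12.1% of AAV-sgSCR CD8 cells. They held 0.153%, 0.611% and 0.458% of mock ones. Highest in AAV-sgSCR CD8 cells were the neutrophil genes S100a9 (117-fold), S100a8 (109-fold) and Ngp (432 UMIs against 3, 57.1-fold, log2 4.28 to 8.12), then Slc16a11 (492 against 3, 65.0-fold, 4.47 to 8.31) and Nrn1 (56.1-fold). S100a9 was also 78.8-fold higher in NK and ILC1-like cells and counted 149 against 3 times in plasmacytoid dendritic cell-like cells (76.1-fold, 4.68 to 8.54), in a library rich in neutrophils. Lowest were H60b (3 against 31 UMIs, 26.1-fold, -7.06 to -3.02), Tppp3 (20.2-fold), Cnga1 (18.9-fold), Utp14b (14.7-fold) and S1pr5 (12.3-fold).

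All 15 naive and memory genes were lower in AAV-sgSCR CD8 cells (median -2.02, with Ccr7 at -2.70 and S1pr1 at -2.48). Higher were 13 of 18 inhibitory receptor genes (1.28, with Cd244a at 3.22 and Cd200 at 2.76), 9 of 13 residency genes (1.58, with Xcl1 at 2.43 and Itga1 at 2.19) and 15 of 20 cytotoxic genes (0.71, with Klrc1 at 1.98 and Gzma at 1.90, but Cx3cr1 at -2.02). Only clusters T2 and T4 had at least 100 cells in both libraries, so lists inside the other clusters, also T1, were not compared. Inside T2 and T4 naive genes were also lower (-0.45 and -0.66). Inhibitory (-0.83 and -0.50) and cytotoxic genes (-0.83 and -0.25) were lower there too, and residency genes were at 0.23 and -0.46. Of the fixed genes Cxcr6 was at 1.90, Tox at 1.46, Cd8a at 1.08, Gzmb at 0.38, Cd8b1 at 0.06, Ifng at -0.02, Prf1 at -0.18, Mki67 at -0.36 and Thy1 at -0.86.

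Higher on balance were also myeloid inflammatory (8 of 9, 1.23), macrophage (9 of 13, 0.87, with Spp1 at 5.29), regulatory T cell (7 of 11, 0.67), chemokine (6 of 10, 0.49), oxidative phosphorylation (18 of 20, 0.29), glycolysis (12 of 16, 0.28), NRF2 target (14 of 20, 0.26) and MHC class I genes (11 of 13, 0.15). Spp1 led CD8 cluster T13, which held 238 AAV-sgSCR and 3 mock cells. Immediate early genes were lower in 15 of 19 (-0.49), proliferation genes in 15 of 20 (-0.35, with Nusap1 at -0.64) and endoplasmic reticulum stress genes in 10 of 18 (-0.10). Near 0 were the type I interferon list (10 of 26 higher, -0.08), interferon gamma (9 of 19, -0.0036), MHC class II (5 of 8, 0.02), mitochondrial transcripts (6 of 13, -0.04) and bile acid receptors (4 of 7, 0.02). T helper factors were higher in 4 of 7 (0.39). Taking CD8 cells by transcripts turned the proliferation list to 1.14, Mki67 to 1.35 and Gzmb to -0.62, thinning turned Mki67 to 0.0701, and resolution 0.5 turned T helper factors to -0.0379. Over all settings the medians ran from 0.25 to 1.21 for macrophage, 0.70 to 1.73 for residency, 0.0939 to 0.98 for chemokine, 0.50 to 1.52 for regulatory T cell, 0.22 to 0.53 for glycolysis, 0.0537 to 0.19 for MHC class I and -0.67 to 3.17 for MHC class II genes.

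In the other classes, proliferation genes were higher in AAV-sgSCR plasmacytoid dendritic cell-like cells (20 of 20, 3.43, with Pclaf at 5.02 and Cenpf at 4.64), NK and ILC1-like cells (13 of 13, 2.03) and B cell-like cells (17 of 18, 1.42). Over all settings these medians ran from 2.88 to 4.01, from 0.61 to 2.24 and from 0.26 to 6.68. Mock B cells lay in clusters 1 (1315) and 2 (1350), and AAV-sgSCR ones in 2 and 28. Inside cluster 2 the proliferation median of AAV-sgSCR was -0.25 (-0.60 to 0.17) over 6 genes, and inside cluster 6 it was 0.69 (0.0107 to 1.35) over 11. MHC class II genes were lower in B cell-like cells (8 of 8, -0.82), with -0.11 inside cluster 2 and -0.32 inside cluster 6, and cytotoxic genes were lower in NK and ILC1-like cells (17 of 20, -0.49, with Ccl4 at -1.92, Prf1 at -1.56 and Gzma at -1.40). Cluster 0 held 59.9% of the mock and 40.6% of the AAV-sgSCR NK and ILC1-like cells, and the cytotoxic median was -0.54 inside it and -0.67 inside cluster 7. A median-of-ratios scaling placed the middle of all NK genes at -0.17, and the cytotoxic median lies below that. Immediate early genes were lower in plasmacytoid dendritic cell-like (17 of 17, -1.33, with Egr1 17.4-fold and Hsph1 8.16-fold lower), B (15 of 19, -0.95, with Nr4a1 7.66-fold lower) and NK and ILC1-like cells (17 of 19, -0.67, with Sgk1 8.25-fold lower). Bile acid synthesis genes were lower in 2 of 3 measured cases in B cell-like (-0.30) and in plasmacytoid dendritic cell-like cells (-0.97). Camp, a neutrophil granule gene, was 170-fold higher in AAV-sgSCR B cell-like cells.

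The comparison of AAV-sgBaat with mock sets the Baat guide livers against the same reference. Their CD8 share of T-like cells was 37.0% against 40.1%, with overlapping intervals, beside more Dntt/Arpp21 cells (54.5% against 0%) and fewer CD4 (2.10% against 29.0%) and natural killer T cell-like cells (2.61% against 24.4%). Without the Dntt/Arpp21 cells the CD8 share was 81.3% against 40.1%. Taken as a whole class, the CD8 cells carried more RNA of cytotoxic and residency genes than mock cells and less of naive genes, with Pdcd1 at a log2 ratio of 1.95, Gzma at 1.64 and Tcf7 at -1.30.

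Neutrophil-like cells were 19.1% of the cells that were not T-like, against 0.273% in mock, classical monocyte-like cells 15.8% against 1.76%, macrophage-like cells 7.16% against 0.0496% and B cell-like cells 14.0% against 71.2%. In CD8 cells the highest ratios were those of S100a9 (66.9-fold), S100a8 (61.9-fold), Camp (75 against 2 UMIs, 54.2-fold, log2 3.86 to 8.83), Ngp (58 against 3, 27.9-fold, 3.19 to 7.12) and Cd200r2 (89 against 3, 42.9-fold, 3.83 to 7.73). S100a9 was 35.4-fold higher in NK and ILC1-like cells too. Lowest were the gut-homing receptor gene Ccr9 (9.12-fold), the B cell gene Cd79a (7.61-fold), Zbtb16 (2 against 32 UMIs, 11.1-fold, -6.57 to -1.50), Tppp3 with the same counts, and H60b (1 against 31, 21.4-fold, -9.77 to -1.84).

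Naive and memory genes were lower in 14 of 15 cases (-1.39, with Ccr7 at -2.41 and Bach2 at -1.87). Cytotoxic genes were higher in 16 of 20 (0.72), residency genes in 11 of 13 (0.97, with Itga1 at 2.32 and Xcl1 at 2.13), oxidative phosphorylation genes in 20 of 20 (0.38), glycolysis genes in 13 of 15 (0.36) and myeloid inflammatory genes in 6 of 6 (1.28). Inhibitory receptor genes were split, with 9 of 17 higher and a median of 0.06 (-0.08 to 0.46), from Cd244a at 2.85 to Rgs16 at -2.13. The CD8 cells lay in different clusters, with T1 holding 45.6% of mock and 7.75% of AAV-sgBaat cells, T12 0.611% and 24.3%, and T2 18.2% and 37.6%. Inside T2 and T4 the medians were -0.44 and -0.72 for naive, -0.42 and -0.0899 for cytotoxic, 0.63 and -0.0777 for residency and -0.80 and -0.34 for inhibitory receptor genes. All 13 mitochondrial transcripts were lower (-0.78). Cxcr6 was at 1.78, Cd8a at 0.87, Tox at 0.67, Gzmb at 0.67, Ifng at 0.36, Cd8b1 and Mki67 at -0.07, Thy1 at -0.30 and Prf1 at -0.40.

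The remaining medians were 0.23 for MHC class I (9 of 13 higher), 0.15 for interferon gamma (11 of 18), 0.15 for NRF2 targets (9 of 18), 0.15 for endoplasmic reticulum stress (11 of 17), 0.58 for T helper factors (3 of 4), 0.32 for chemokines (5 of 9), 0.28 for regulatory T cell genes (4 of 8) and 0.10 for macrophage genes (6 of 10). Proliferation (9 of 20, -0.04, with Tyms at 1.39), type I interferon (10 of 24, -0.07), immediate early (8 of 19, -0.07), MHC class II (3 of 7, -0.03) and bile acid receptor genes (2 of 6, -0.28) were at or below 0. The inhibitory median was 0.90 in cells thinned to equal depth, 0.81 over members with at least 100 UMIs and -0.66 in CD8 cells taken by transcripts. Those cells also turned cytotoxic genes to -0.94, residency genes to -0.62, MHC class I genes to -0.83, Tcf7 to 0.64, Tox to -0.34, Cd8a to -0.33, Gzma to -0.15, Ifng to -1.35 and Gzmb to -1.59. At resolution 0.5 the T helper and regulatory T cell medians turned to -0.12 and -0.15. Over all settings the medians ran from -1.40 to 2.75 for MHC class II, -0.068 to 2.54 for proliferation, -1.18 to 0.27 for interferon gamma, -0.70 to 0.39 for type I interferon, -0.53 to 0.50 for chemokine, 0.11 to 0.58 for NRF2 target and 0.35 to 1.03 for oxidative phosphorylation genes.

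In B cell-like cells proliferation genes were higher in 16 of 18 cases (2.69) and MHC class II genes lower in 8 of 8 (-0.46). Inside cluster 2 these medians were 0.61 (-0.18 to 1.06) and 0.12 (0.0426 to 0.16). Inside cluster 6 they were 0.65 (0.34 to 0.93) and -0.32 (-0.47 to -0.17). Over all settings the proliferation median of B cell-like cells ran from 0.88 to 6.69. Rag1 was 107-fold higher there, at 60.8 CPM (90.5 in AAV-sgSCR), with AAV-sgBaat cells in clusters 2 and 28. In NK and ILC1-like cells proliferation genes were higher in 9 of 10 (0.69) and cytotoxic genes lower in 15 of 19 (-0.42), with -0.28 inside cluster 0 and -0.53 inside cluster 7.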

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

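Each group is 1 library pooled from 3 tumor samples, so group, library, depth, sort and mix cannot be told apart, and intervals cover counting error only. No paired analysis was possible because no animal or sample is shared between libraries. The 3 libraries differ in depth and in the share of barcodes with mixed lineages (5.01%, 17.9% and 31.8% for mock, AAV-sgSCR and AAV-sgBaat). Several settings were chosen after the data were seen, as named below. A setting counts as moved where its value left the 95% interval of the reported value, or turned where the sign changed and that interval left out 0, and the cause was not tested unless stated. Over all settings, 25 of 30 CD8 shares, 170 of 435 class shares, 4 of 6 hepatocyte RNA values and 9 of 9 tag values moved. Shares cannot change sign, so their order was compared instead, a count added after seeing the data: in 18 of 155 settings of a class the AAV-sgBaat and AAV-sgSCR shares stood in the opposite order. These were 4 for plasmacytoid dendritic cell-like, 2 each for NK and ILC1-like, CD4 T cell-like, classical monocyte-like and progenitor-like, and 1 each for B cell-like, natural killer T cell-like, gamma-delta, regulatory T cell-like, immature neutrophil-like and plasma cell-like cells. Of 1330 gene values 216 moved and 18 turned, and of 1685 list values 333 moved and 40 turned. Another seed kept 92.4% of 16254 cells in their class, resolution 0.5 kept 90.7% and resolution 2 kept 85.9%. The CD8 share of AAV-sgBaat stayed below that of AAV-sgSCR in each setting. Below, values are in CD8 T cell-like cells and in log2 units unless a class or a percentage is given, and groups are named in the order mock, AAV-sgSCR, AAV-sgBaat.

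Cell filters. With every deposited barcode the CD8 share was 77.9% in AAV-sgSCR and 27.6% in AAV-sgBaat, the Dntt/Arpp21 share 6.41% and 62.66%, the neutrophil share 22.8% and 13.6%, and the AAV-sgSCR B cell share 20.1%. AAV-sgBaat against AAV-sgSCR turned to 0.10033 for proliferation in cDC1-like and to -0.495 for cytotoxic genes in classical monocyte-like cells, and the hepatocyte-like class was not named. With the stricter filter the CD8 share was 35.6%, 78.9% and 39.6%, the B cell share 62.1%, 7.007% and 12.4%, the Dntt/Arpp21 share 2.28% in AAV-sgSCR and 47.02% in AAV-sgBaat, and the AAV-sgBaat neutrophil share 11.9%. The cytotoxic list was -0.13 and the naive list 0.92 against AAV-sgSCR, and the naive list of AAV-sgSCR against mock -2.36. Cytotoxic genes in B cell-like cells of AAV-sgBaat against mock turned to -0.28, and proliferation in neutrophil-like cells against AAV-sgSCR to -0.11.

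Doublets and mixed barcodes. The setting with doublets kept also kept mixed-lineage barcodes, so its values are not those of doublets alone. There the CD8 share was 36.2%, 71.8% and 25.1%. The B cell share was 15.6% in AAV-sgSCR and 7.29% in AAV-sgBaat, and the AAV-sgBaat neutrophil share 11.04%. The naive list was -2.18 for AAV-sgSCR and -1.65 for AAV-sgBaat against mock. AAV-sgBaat against AAV-sgSCR turned for Gzma (0.0481), Cd3e in cDC1-like cells (-0.66), MHC class II in NK and ILC1-like cells (0.31), residency in B cell-like cells (-0.96), and cytotoxic (-0.79) and proliferation genes (0.397) in cDC1-like cells. MHC class II in NK and ILC1-like cells of AAV-sgSCR against mock turned to -0.0340. Hepatocyte-like and patrolling monocyte-like cells were not named. With only mixed-lineage barcodes kept, a setting added after seeing the data, the CD8 share was 36.6%, 71.2% and 28.5%, and in AAV-sgBaat the Dntt/Arpp21 share was 48.9%, the B cell share 6.51% and the neutrophil share 10.98%. Against mock the cytotoxic list of AAV-sgSCR was 0.78 and its naive list -2.18, the regulatory T cell list of AAV-sgBaat turned to -0.0803 and its T helper list in B cell-like cells to 0.24. Against AAV-sgSCR, MHC class II (-0.00378) and cytotoxic genes (-0.13) in classical monocyte-like cells, proliferation in cDC1-like cells (0.393), residency in B cell-like cells (-1.05) and residency in progenitor-like cells (-0.0158) turned. Hepatocyte-like cells were not named.

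Clustering. Another seed gave CD8 shares of 84.4% in AAV-sgSCR and 30.9% in AAV-sgBaat, neutrophil shares of 19.4% and 11.5%, and an AAV-sgBaat Dntt/Arpp21 share of 62.7%, since 435 barcodes left unassigned joined that class. At resolution 0.5 the CD8 share was 42.6%, 84.2% and 29.9%, the neutrophil share 19.1% in AAV-sgSCR and 11.1% in AAV-sgBaat, and the AAV-sgBaat Dntt/Arpp21 share 63.6%, since 464 unassigned barcodes joined it. T helper factors turned to -0.0379 for AAV-sgSCR and -0.12 for AAV-sgBaat against mock, and regulatory T cell genes of AAV-sgBaat against mock to -0.15. Against AAV-sgSCR proliferation turned to -0.21 in B cell-like and to 0.43 in cDC1-like cells, and MHC class II in plasmacytoid dendritic cell-like cells of AAV-sgSCR against mock turned to 0.35. Hepatocyte-like, patrolling monocyte-like and macrophage-like cells were not named. At resolution 2 the gamma-delta share was 5.58% in mock and 6.69% in AAV-sgSCR, since 72 and 55 NK and ILC1-like cells joined it, and the CD8 share was 35.9%, 74.7% and 27.7%, the B cell share 20.9% in AAV-sgSCR and 16.2% in AAV-sgBaat, and in AAV-sgBaat the Dntt/Arpp21 share was 58.3% and the neutrophil share 17.4%. The cytotoxic list of AAV-sgBaat against mock was 0.82, and in NK and ILC1-like cells Mmp9 of AAV-sgBaat against mock turned to 1.95 and regulatory T cell genes of AAV-sgSCR against mock to -0.13.

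Class definitions. Taking CD8 cells by transcripts per cell takes every kept barcode with Cd3 and CD8 UMIs and no Cd4 UMI, whatever its cluster. It takes in Dntt/Arpp21 cells and barcodes of other classes, also unassigned ones. Shares are then of all kept barcodes with a Cd3 UMI. CD8 shares were 29.7%, 64.2% and 44.98%. Against AAV-sgSCR, G0s2 (-1.14), Gzmb (-0.97), Ifng (-1.12), naive (-0.30) and immediate early genes (-0.19) turned, and the cytotoxic list was -1.30 and the inhibitory list -1.71. For AAV-sgSCR against mock, Gzmb (-0.62), Mki67 (1.35) and proliferation (1.14) turned, and the cytotoxic, inhibitory and naive lists were 0.31, 0.91 and -1.60017. For AAV-sgBaat against mock, Cd8a (-0.33), Tcf7 (0.64), Tox (-0.34), Gzmb (-1.59), Gzma (-0.15), Ifng (-1.35), cytotoxic (-0.94), residency (-0.62), MHC class I (-0.83), regulatory T cell (-1.10379) and T helper genes (-0.5046) turned, and the inhibitory and naive lists were -0.66 and -2.43. The other definitions were added after seeing the data. Without Dntt/Arpp21 cells the CD8 share was 84.8% in AAV-sgSCR and 81.3% in AAV-sgBaat. Unassigned barcodes counted as T-like gave a CD8 share of 29.8% in AAV-sgBaat, and counted as not T-like a B cell share of 11.5% and a neutrophil share of 15.8%.

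Counting. Thinned to equal depth, Gzmb against AAV-sgSCR turned to -0.0175 and Mki67 of AAV-sgSCR against mock to 0.0701. Against mock the inhibitory list was 1.59 in AAV-sgSCR and 0.897577 in AAV-sgBaat, and the naive list of AAV-sgBaat -1.54. In classical monocyte-like cells against AAV-sgSCR, Ms4a3 and Dmkn turned to 0.69 and myeloid inflammatory genes to -0.0286. Cytotoxic genes in cDC1-like cells turned to -0.115. Type I interferon genes in NK and ILC1-like cells of AAV-sgBaat turned to -0.111 against AAV-sgSCR and to -0.0769 against mock. With equal weight per cell, proliferation in NK and ILC1-like cells against AAV-sgSCR turned to 0.106. With list members of at least 100 UMIs, the cytotoxic list of AAV-sgSCR against mock was 0.83, the inhibitory list of AAV-sgBaat against mock 0.81, and type I interferon in its B cell-like cells turned to -0.0457. With members of at least 5 UMIs, T helper factors of AAV-sgSCR against mock turned to -0.0805, regulatory T cell genes of AAV-sgBaat against mock to -0.16 and T helper factors in its B cell-like cells to 1.09863. Median-of-ratios scaling added 0.17 (AAV-sgSCR against mock) and 0.14 (AAV-sgBaat against mock) to each log2 ratio in NK and ILC1-like cells and 0.16 in neutrophil-like cells against AAV-sgSCR, and scaling without mitochondrial and ribosomal genes added 0.21 and 0.15 in the NK comparisons. Taken inside cluster 2, a split added after seeing the data, MHC class II in B cell-like cells was 0.24 against AAV-sgSCR, and against mock -0.11 in AAV-sgSCR and 0.12 in AAV-sgBaat, and inside cluster 6 it was -0.0175, -0.32 and -0.32, so the sign of AAV-sgBaat against mock depends on the cluster.

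Tags and hepatocyte RNA. CD8 cells above 3 CD90.1 UMIs were 99.69%, 99.75% and 99.72%, and above 50 they were 5.19%, 61.4% and 47.9%. With at least 100 UMIs of the 2 CD90 tags together and more CD90.1 than CD90.2, a threshold chosen after seeing the data, they were 1.68%, 55.5% and 28.9%. Hepatocyte markers without Alb and Apoa1 took 0.952 of 10000 UMIs in mock and 6.04 in AAV-sgSCR, and over every barcode the full set took 6.22 in AAV-sgSCR and 2.56 in AAV-sgBaat.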

Other observations

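Of the Trbv UMIs in CD8 T cell-like cells, Trbv29 took 16.4% in mock (22 of 134), 81.1% in AAV-sgSCR (640 of 789) and 64.5% in AAV-sgBaat (120 of 186). In cluster T12 it took 98.2% in AAV-sgSCR and 95.9% in AAV-sgBaat, and in clusters T8 and T13 of AAV-sgSCR 93.5% and 94.3%. Cluster T10, not CD90.1-high by its median, also had it at 84.4% in AAV-sgSCR and 78.3% in AAV-sgBaat (18 of 23 UMIs). The leading Trav gene differed, with Trav9-2 at 43.0% in CD90.1-high CD8 cells of AAV-sgSCR and Trav21-dv12 at 48.6% in those of AAV-sgBaat, but both genes were found in both libraries. In cluster T12 Trav9-2 took 46.6% in AAV-sgSCR and 26.1% in AAV-sgBaat, and Trav21-dv12 14.3% and 49.3%. The source of the CD90.1 cells is not given in the sources used here.

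The tags also marked cells of other lineages. At least 100 UMIs of the 2 CD90 tags together with more CD90.1 than CD90.2 were found in 64.7% of AAV-sgBaat and 42.0% of AAV-sgSCR neutrophil-like cells, and in 79.4% and 41.5% of macrophage-like cells, so the tag alone does not mark T cells. UMIs of the added SV40 feature numbered 85 in mock, 23 in AAV-sgSCR and 2 in AAV-sgBaat, in 42, 13 and 2 barcodes.

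Of the tests below, those of polyclonal thymocytes, of free RNA behind the Dntt/Arpp21 cells and of 2 cells in 1 droplet were chosen only after the result was seen. The Dntt/Arpp21 cells of the AAV-sgBaat library may be polyclonal thymocytes, evenly spread free RNA, or cells of the same donor pool as the CD90.1-high CD8 cells. Trbv29 took 81.5% of their Trbv UMIs (77.3% to 85.3%), which counts against polyclonal thymocytes. Over all 7094 filtered AAV-sgBaat barcodes the UMIs of Dntt, Arpp21, Gm525 and Lgals7 had a variance of 28.2 times their mean (7.26 with depth taken into account). Dntt and Arpp21 define the class, and Gm525 and Lgals7 are leading genes of its clusters. Their uneven spread therefore restates the clustering and is no separate evidence against free RNA. The leading alpha gene of the Dntt/Arpp21 cells, Trav6-7-dv9, took 45.6% of their few Trav UMIs (26 of 57, 32.4% to 59.3%). It took 6.30% (3.99% to 9.39%) in CD90.1-high CD8 cells of AAV-sgSCR, which counts against 1 shared clone. A shared donor pool was not decided. Its prediction asked for 1 alpha gene to hold most Trav UMIs in both sets, and in those CD8 cells the leading gene took 43.0%. The beta gene and the tag are shared and the leading alpha gene also differs between the CD90.1-high CD8 cells of the 2 libraries, which hold several alpha genes each, so a common donor with other alpha chains, an expanded or malignant clone and an effect of the Baat guide all stay open.

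T cell transcripts in barcodes of other lineages could come from free RNA alone or from 2 cells in 1 droplet alone. At least 2 Cd3 UMIs were found in 56.2% of AAV-sgBaat, 35.9% of AAV-sgSCR and 24.7% of mock barcodes with monocyte or macrophage transcripts. The variance of Cd3 and T cell receptor UMIs in AAV-sgBaat barcodes with neutrophil transcripts was 90.23 times the mean (15.8 with depth taken into account, 1294 barcodes). These barcodes were chosen by neutrophil transcripts alone, before mixed barcodes were removed. They can therefore include T cells that picked up free neutrophil RNA, and such a mix would also give a large variance. Free RNA alone was thus not decided by this value. Immature B cells can make Dntt themselves, so B cell-like cells were taken from clusters 2 and 6, shared with mock, and only without a Cd3 or receptor constant UMI: there Dntt, Arpp21, Gm525 and Lgals7 were 69.9-fold (22.3-fold to 289-fold) higher in AAV-sgBaat than in mock, and 30.9-fold higher in AAV-sgBaat neutrophil-like cells than in those mock cells, against paired cells alone. Both sources together, or T cells bound to or taken up by other cells, were not tested apart.

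The lower inhibitory receptor list in AAV-sgBaat CD8 cells could come from fewer cells of CD90.1-high clusters, from lower depth, or from lower levels in each cell. Inside the 3 clusters with at least 100 cells in both libraries the median farthest from 0 was 0.23, against -0.58 over the whole class. Smaller clusters that held cells of both libraries, such as T1 and T10, were not compared. Other clusters were filled unequally, also T7, low in CD90.1 (3.16% of AAV-sgSCR and 0.277% of AAV-sgBaat CD8 cells). Clusters were drawn from the same RNA, and list members were leading genes of clusters that AAV-sgBaat hardly filled (Pdcd1 in T8, Cd200 in T13, Havcr2 in T7). These medians therefore cannot tell a different mix of clusters from lower levels in each cell. Thinned to equal depth with the classes kept fixed, the median was -0.62. The ratio is already scaled to total UMIs, so this counts only against an effect of depth on the counting itself. Depth could also act through the filters, the removal of mixed barcodes and the clustering, which thinning did not touch. Whether the Baat guide, the source of the CD90.1 cells or the sort set the mix of clusters was not tested.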
